A study of Mus musculus with 15 samples.

How the data were processed

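The gene names used here rest on an inference about the order of the deposited table, and every named result depends on it. In the table as deposited, genes known to work together did not vary together. The values were therefore paired again with the identifiers on the evidence of the values themselves, a choice made after seeing the data. No header or label states this displacement. Counts of probe sets do not depend on it, whereas gene names and gene lists do.

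Affymetrix arrays measured RNA from 3 groups of mouse heart cells with 5 arrays each, 15 arrays in all. CF are fibroblasts of unstressed hearts, aCF are fibroblasts of hearts taken 5 days after myocardial infarction, and EpiSC are epicardial stromal cells of hearts taken 5 days after infarction. The mice were C57BL/6 aged 8 to 12 weeks, and the series design text calls the arrays of a group biological replicates. Per the labels' protocols, hearts were perfused with collagenase, and shear released the EpiSC from the heart surface. The atria were removed for CF and aCF, and strainers and a slow spin separated heart muscle cells from the fibroblast fractions. A sort or gate after the pelleting step is not given in the sources used here. Per the labels, 1 ng of RNA was amplified and labelled with biotin.

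The deposited values are log2 expression values that the authors centred on each probe set's median over the 15 arrays. Per the series design text, the authors used GeneSpring GX 12.5, normalized probe signals by quantiles, summarized them with an exon-level RMA algorithm, and then applied that baseline step. No header names the base of the logarithm, so base 2 is inferred from the RMA method and the range of the values, -4.77 to 5.52. Every array and every probe set has a median of 0, so the level of a probe set and its signal over background are lost. The design text also names a filter at the 20th percentile of raw signal. It could not be applied to centred values, and all 22206 rows were tested. The number of arrays limits the precision.

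The pairing used the deviations of each array from its group mean, so that differences between groups played no part. The 26 cell cycle genes on chromosomes 1 to 9 and X had a mean pairwise correlation of -0.0078 as deposited. At an offset of 6900 rows it was 0.283, against at most 0.108 at any other of 10353 offsets and at most 0.111 after shuffling the rows. From chromosome 10 on, an extra offset of 3 rows, the number of identifiers of a separate naming type, gave a correlation of 0.562 with the list profile, against -0.071 without it. That is the highest of 21 extra offsets tried, on 5 cell cycle members only. The next 3 checks left the cell cycle list out. The 970 olfactory and vomeronasal receptor probe sets had a median SD within groups of 0.101 after pairing and 0.181 as deposited, and 0 of 9120 offsets gave a lower one. For 25 pairs of probe sets of the same gene, the median correlation over the arrays was 0.586 after pairing and -0.068 as deposited. Of the 35 other gene lists, 19 exceeded the 95th percentile of 1000 random lists after pairing and 0 did so as deposited. On each of 12 chromosomes the pairing, extra offset included, gave the highest correlation of 51 offsets. That check used 11 lists selected for varying together after pairing, the cell cycle list among them, so it is not independent. The search also found 5 of 5 offsets planted by rotating the real rows. The peak moves with the rows, so this checks the code and is no evidence for the pairing.

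Pairing gave 15306 of the 22206 rows an identifier. The first 6900 rows of values have no identifier here and stay unnamed. What they measure was not checked, and control or normalization probe sets may be among them. They stay in the counts, where they supply 5 of 148 probe sets past the threshold for EpiSC against aCF, 14 of 340 for aCF against CF and 81 of 647 for EpiSC against CF. The last 6900 identifiers have no values here. These cover the later part of chromosome 11, of whose 1629 probe sets 982 were paired, and chromosomes 12 to 19. Genes there, Acta2 among them, were not analysed here. Pdgfra had no value under its name after pairing either, and the reason was not examined. The platform annotation gives 19572 probe sets a single symbol, 0 several and 2634 none, and all 19572 matched the reference gene table. Of the paired probe sets 13493 carry a name, covering 13481 genes. For genes with more than 1 paired probe set the first by identifier was used.

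Each comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on the deposited log2 values of the groups compared. The P values were Bonferroni-adjusted over all 22206 rows with a threshold of 0.05. EpiSC against aCF and aCF against CF are the comparisons in the design text, and EpiSC against CF was added as secondary. All tests were 2-sided. Gene lists were tested with camera in limma at a preset correlation of 0.01, adjusted by Benjamini-Hochberg over the 36 of 37 lists with at least 5 measured members. The camera test was repeated with a correlation estimated from the data. The fry test asks another question, whether the genes of a list move on balance in 1 direction, without comparing them with other genes, so a fry call does not repeat a camera call. Members of a list were counted after adjustment over all rows and adjusted over the list alone. Tables were built with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots with matplotlib 3.10.9.

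The groups, tests, lists and most alternatives were fixed before the data were examined. So was the rule for named genes in each main comparison. It takes the 8 largest positive and 8 largest negative differences among genes past the threshold whose groups do not overlap, leaving out predicted genes. It adds up to 4 members of each described list with the smallest P, and Wt1, Tbx18, Tcf21, Pdgfra, Postn, Acta2 and Col1a1 whatever their values. For EpiSC against CF it takes at most 2 members per list. Which lists are described was chosen after seeing the data. The alternatives were Benjamini-Hochberg adjustment, a 2-fold minimum, quantile normalization, 1 fit of all 3 groups, the replicate number as a block, a trended and robust fit, array weights, averaged probe sets, and leaving out each array. Those chosen after seeing the data were the paired rows alone, medians of the paired rows subtracted, the identifiers as deposited, and the fit without aCF4 and aCF5. These 2 arrays were picked for their place on the first principal component and their lower heart muscle markers. Quantile normalization was applied to centred values that the authors had already normalized by quantiles before centring. It gives every array the same spread of deviations, which can shrink large differences by itself. The trended fit had only the mean centred value of a row to follow, since levels are lost. Losses under these 2 settings therefore may not mean that a call is weak. The main fit was tested on simulated data with 200 planted changes. For EpiSC against aCF it recovered 57% of changes of 1 log2 unit and 95% of changes of 2 units, for aCF against CF 76% and 99%, and for EpiSC against CF 71% and 93%. There were 0 false calls among 22006 unchanged rows in each simulation. The noise was normal, with the SD of each row, and drawn independently for each row and array. It held no variation shared between rows or arrays, so these rates need not hold for the real arrays.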

Results

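Expression was measured in 15 samples of mouse heart cells, 5 per group. CF were fibroblasts of unstressed hearts, aCF were fibroblasts of hearts 5 days after myocardial infarction, and EpiSC were epicardial stromal cells of hearts 5 days after infarction. Values are log2 expression relative to the median of the 15 arrays, so differences between groups are measured and absolute levels are not. Gene names rest on an inferred displacement of 6900 rows between identifiers and values, which no source states. It covers 15306 of 22206 rows.

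**Figure D1:**
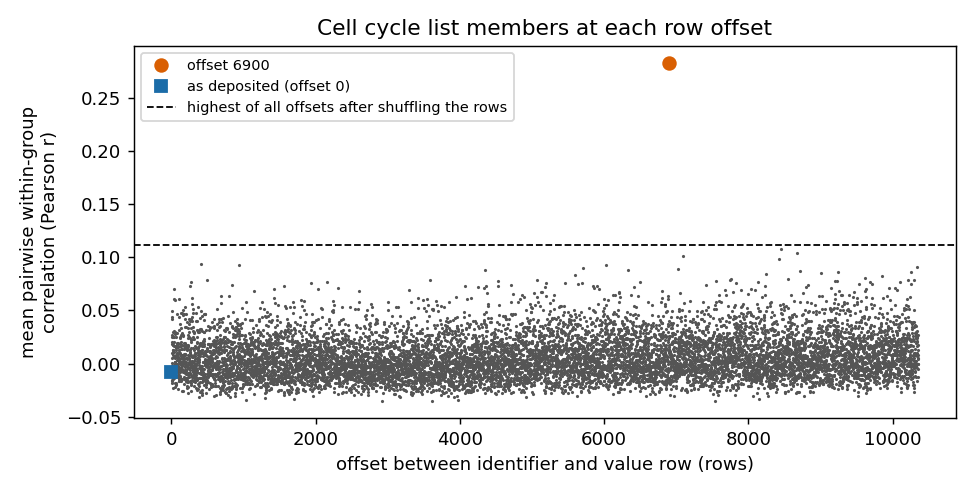
Mean pairwise Pearson correlation within groups of the 26 cell cycle list members on chromosomes 1 to 9 and X (vertical axis) at each of 10353 row offsets between identifier and value (horizontal axis). The correlation is 0.283 at an offset of 6900 rows and -0.0078 as deposited, and the dashed line marks the highest value after shuffling the rows, 0.111.

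The arrays separated by group over the paired rows. The first principal component held 51.3% of the variance and the second 16.9%, and for 15 of 15 arrays the most correlated other array was of the same group. Correlations within groups lay between 0.743 and 0.845 for CF, 0.551 and 0.671 for EpiSC, and 0.213 and 0.540 for aCF. On the first component aCF4 (6.35) and aCF5 (4.48) lay on the EpiSC side of aCF1 (-4.51), aCF2 (-1.65) and aCF3 (-3.12). No pair of arrays shared more than 2.45% of identical values, so none was a duplicate.

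**Figure D2:**
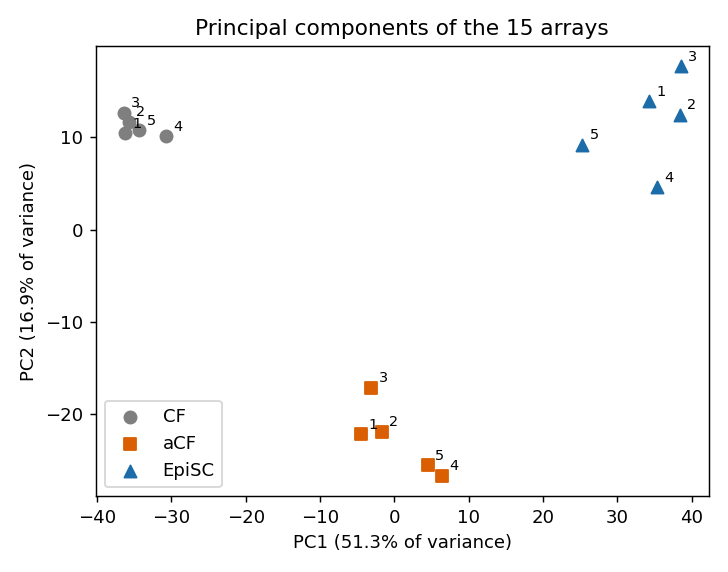
First and second principal components of the 15 arrays over the paired rows, with 1 point per array, shaped and coloured by group and numbered by replicate. The CF arrays lie between -36.4 and -30.8 on the first component and the EpiSC arrays between 25.3 and 38.5, with the aCF arrays between them.

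The comparison of EpiSC with aCF asks how cells of the activated heart surface differ from fibroblasts of the injured ventricle. Per the protocols, shear released the EpiSC, while the aCF were prepared without atria and with strainers and a slow spin. Cell type and isolation therefore differ together here, and their effects cannot be told apart. EpiSC expressed more of the epicardial transcription factor Wt1 (log2 difference 2.01 ± 0.18, SE, n = 5 arrays per group) and of the mesothelial secreted protein Dmkn (3.64 ± 0.32). They also expressed more of Serpinb2, an inhibitor of plasminogen activators (5.02 ± 0.25, a 32.4-fold difference). The aCF samples held more RNA of Fmod, a collagen-binding proteoglycan (-3.14 ± 0.22), of the mural cell gene Rgs5 (-3.58 ± 0.21) and of Ptprb, an endothelial receptor phosphatase (-3.09 ± 0.15). Whether fibroblasts or other cells in these samples supplied the Rgs5 and Ptprb RNA was not tested. By camera at its preset correlation, cell cycle, glycolysis and interferon-stimulated genes were shifted upward in EpiSC, and activated fibroblast, basement membrane and mural genes downward. With an estimated correlation each of these calls was lost (adjusted p = 0.0989, and adjusted p = 0.108 for the basement membrane). In limma's moderated test with Bonferroni adjustment, 148 of 22206 probe sets passed, 89 higher and 59 lower in EpiSC, of which 130 carried a name. Of 36 gene lists 18 passed camera, 7 shifted upward and 11 downward, and 0 passed with an estimated correlation (12 at an unadjusted p under 0.05), while fry, which makes no comparison with other genes, called 24. In 12.4% of the paired rows the arrays of the 2 groups did not overlap, against 0.794% by chance.

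Among the largest increases in EpiSC were Serpinb2 (adjusted p = 2.72e-05), the iron-siderophore binding protein Lcn2 (3.76 ± 0.28, adjusted p = 0.00188) and Nkain4 (3.17 ± 0.24, adjusted p = 0.00248). Others were the platelet chemokine Ppbp (3.15 ± 0.24, adjusted p = 0.00181) and the adhesion molecule Chl1 (2.76 ± 0.23, adjusted p = 0.0057). The tight junction protein F11r (2.81 ± 0.27, adjusted p = 0.0226) and the transcription factor Gata5 (2.70 ± 0.26, adjusted p = 0.024) were also higher. Among the largest decreases were Rgs5 (adjusted p = 0.000162), Fmod (adjusted p = 0.000888), Ptprb (adjusted p = 1.91e-05), Olfr558 (-2.67 ± 0.19, adjusted p = 0.00109), the imprinted gene Mest (-2.42 ± 0.15, adjusted p = 0.000298) and the pericyte gene Higd1b (-2.10 ± 0.16, adjusted p = 0.00235). Rgs4 (-2.54 ± 0.25, adjusted p = 0.0294) and the Wnt antagonist Sfrp1 (-2.14 ± 0.21, adjusted p = 0.0265) were lower too. For each gene named as past the threshold in this comparison, all 5 EpiSC arrays lay on the same side of all 5 aCF arrays. The naming rule required this of the largest differences. Several calls needed nearly all arrays. That of F11r held in 2 of 10 omissions (without EpiSC4 or aCF3, p up to 0.134 otherwise), that of Rgs4 in 2 (without EpiSC4 or EpiSC5, up to 0.177), and those of Gata5 (up to 0.15) and Sfrp1 (up to 0.164) only without EpiSC4. Quantile normalization ended the calls of F11r (0.245), Chl1 (0.198), Lcn2 (0.1) and Higd1b (0.0957), and a trended and robust fit that of Higd1b (0.821). Quantile normalization also moved sizes, which giving each array the same spread of centred values can do by itself. The log2 difference became 3.45 for Serpinb2, 2.97 for Lcn2, 2.44 for Nkain4, 2.36 for Ppbp, 2.14 for F11r, 2.74 for Dmkn and -3.78 for Fmod, each over 1.5 times from the fold above.

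Of 17 measured epicardial and mesothelial markers, 5 rose in EpiSC and 0 fell over all genes tested, and 9 rose and 2 fell adjusted over the list alone (median log2 difference 0.94, camera adjusted p = 9.02e-05). With an estimated correlation the list's adjusted p = 0.0989. The scaffold protein Slc9a3r1 was higher by 2.41 ± 0.14 (adjusted p = 0.000118), Wt1 by 2.01 (adjusted p = 0.00883), Dmkn by 3.64 (adjusted p = 0.00983) and the mesothelial transcription factor Bnc1 by 2.36 ± 0.22 (adjusted p = 0.017). The call of Wt1 was lost without EpiSC1, aCF1, aCF2, aCF4 or aCF5 (p up to 0.0595). That of Dmkn held only without aCF3 or aCF5 (up to 0.0639 otherwise) and that of Bnc1 only without EpiSC5 (up to 0.11). Tbx18, another epicardial gene, differed by 0.10 ± 0.16 and did not pass (adjusted p = 1).

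Activated fibroblast and myofibroblast markers were lower in EpiSC than in aCF. Of 16 measured, 3 fell and 0 rose over all genes tested, and 10 fell and 0 rose adjusted over the list alone (median -1.15, camera adjusted p = 8.54e-09; adjusted p = 0.0989 with an estimated correlation). Sfrp2, a secreted Wnt modulator, fell by 1.23 ± 0.09 on the log2 scale (adjusted p = 0.00114) and the matricellular protein Ccn5 by 1.56 ± 0.14 (adjusted p = 0.0124), the latter call holding only without EpiSC3, EpiSC4, EpiSC5 or aCF1 (up to 0.0815 otherwise). Cilp, a cartilage-type matrix protein, differed by -2.65 ± 0.28 and did not pass (adjusted p = 0.055). The matricellular protein gene Postn (-0.42 ± 0.07) and the collagen gene Col1a1 (-0.24 ± 0.06) did not pass (adjusted p = 1 for each). Of 16 fibroblast lineage markers, 1 fell and 0 rose, and 7 fell and 1 rose adjusted over the list alone (median -0.29, camera adjusted p = 1.22e-05; adjusted p = 0.134 with an estimated correlation). Tcf21, a transcription factor of resident fibroblasts, differed by -0.98 ± 0.19 and did not pass (adjusted p = 1).

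Cell cycle genes were shifted upward in EpiSC. Of 31 measured, 1 rose and 0 fell over all genes tested, and 18 rose and 0 fell adjusted over the list alone (median 0.66, camera adjusted p = 4.15e-13; adjusted p = 0.0989 with an estimated correlation). The replication factor Gins2 rose by 1.06 ± 0.09 (adjusted p = 0.00945), a call lost without EpiSC1, EpiSC2, aCF1, aCF2, aCF3 or aCF4 (up to 0.061). Birc5 (0.82 ± 0.10, adjusted p = 0.236) and Mcm6 (0.72 ± 0.10, adjusted p = 0.824) did not pass. Of 22 glycolysis and hypoxia genes 2 rose and 0 fell, and 10 rose and 0 fell adjusted over the list alone (median 0.49, camera adjusted p = 2.92e-06; adjusted p = 0.0989 with an estimated correlation). The lactate transporter Slc16a3 rose by 1.24 ± 0.10 (adjusted p = 0.00294), and Tpi1, triose phosphate isomerase, by 0.61 ± 0.06 (adjusted p = 0.014), a call that held only without aCF4 (up to 0.0951 otherwise).

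Of 21 interferon-stimulated genes, 0 passed over all genes tested in limma, where 11 lay higher and 0 lower at an unadjusted p under 0.05. Adjusted over the list alone, 9 rose and 0 fell (median 0.34, camera adjusted p = 3.92e-06, fry adjusted p = 0.000205; adjusted p = 0.0989 with an estimated correlation). Oas2 differed by 1.77 ± 0.22 (adjusted p = 0.223) and Irf7 by 1.08 ± 0.12 (adjusted p = 0.109). Of 27 chemokines 1 rose, which was Ppbp, and 5 rose and 1 fell adjusted over the list alone (median 0.24, camera adjusted p = 0.00177; adjusted p = 0.108 with an estimated correlation). The monocyte chemokine Ccl2 differed by 1.47 ± 0.16 (adjusted p = 0.0604) and Cxcl13 by 4.23 ± 0.54 (adjusted p = 0.257), neither past the threshold. Cxcl13 differed by 2.74 after quantile normalization and by 3.59 without aCF4 and aCF5.

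Basement membrane genes were lower in EpiSC, with 3 of 17 fallen and 0 risen, and 8 fallen and 2 risen adjusted over the list alone (median -0.45, camera adjusted p = 0.000219; adjusted p = 0.108 with an estimated correlation). The collagen genes Col4a2 (-1.30 ± 0.09, adjusted p = 0.0006) and Col15a1 (-1.36 ± 0.11, adjusted p = 0.00486) fell. Of 24 growth factors 3 fell and 0 rose, and 6 fell and 1 rose adjusted over the list alone (median -0.11, camera adjusted p = 0.0132; adjusted p = 0.191 with an estimated correlation). Vegfd differed by -1.02 ± 0.10 (adjusted p = 0.028), a call that held only without EpiSC5 (up to 0.174 otherwise), and Igf2 by -1.04 ± 0.11 (adjusted p = 0.0403), a call lost in each of the 10 omissions (0.0555 to 0.236).

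Wnt components, cardiac transcription factors, and hyaluronan and proteoglycan genes did not shift as lists by camera (adjusted p = 0.444, 0.897 and 0.126), but members moved in both directions. By fry, the Wnt list (adjusted p = 0.00422) and the hyaluronan and proteoglycan list (adjusted p = 0.0039) moved downward on balance. The transcription factors did not pass fry (adjusted p = 0.326). The Wnt list had 1 member risen and 3 fallen of 30 (4 and 6 adjusted over the list alone), with a median of 0.047 and a mean of -0.029, while camera ranked it down. The Notch target Heyl fell by 1.73 ± 0.07 (adjusted p = 7.58e-06), 1 of 20 cardiac transcription factors fallen beside 2 risen (7 and 5 adjusted over the list alone). The median of the transcription factors was 0.10 and their mean 0.034, although camera ranked the list down. In the hyaluronan and proteoglycan list 3 of 19 members rose and 2 fell (3 and 6 adjusted over the list alone). The hyaluronan receptor Cd44 rose by 2.43 ± 0.18 (adjusted p = 0.00127), and the proteoglycan Sdc3 fell by 1.03 ± 0.09 (adjusted p = 0.00708).

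Markers of other heart cell types also differed between EpiSC and aCF. Whether such cells were carried over into the samples in different amounts was not tested for this comparison. Of 14 pericyte and smooth muscle markers 2 fell, Rgs5 and Higd1b, and 1 rose, Des (1.68 ± 0.16, adjusted p = 0.0174, held only without EpiSC2, EpiSC4 or aCF4 and up to 0.107 otherwise). Of the mural markers 6 fell and 1 rose adjusted over the list alone (median -0.61, camera adjusted p = 7.23e-06; adjusted p = 0.0989 with an estimated correlation). Of 17 endothelial markers Ptprb fell, and Aqp1, a water channel also known from mesothelium, rose by 2.57 ± 0.17 (adjusted p = 0.000567), with 6 fallen and 1 risen adjusted over the list alone (median -0.33, camera adjusted p = 0.000327; adjusted p = 0.0989 with an estimated correlation). In the macrophage list 0 of 19 markers passed over all genes in limma, where 1 lay higher and 11 lower at an unadjusted p under 0.05. There, 0 rose and 5 fell adjusted over the list alone (median -0.26, camera adjusted p = 0.000117, fry adjusted p = 0.000226; adjusted p = 0.0989 with an estimated correlation). Among 22 heart muscle markers 0 passed over all genes in limma, where 1 lay higher and 9 lower at an unadjusted p under 0.05. Of these markers 1 rose and 3 fell adjusted over the list alone (median -0.21, camera adjusted p = 0.00261, fry adjusted p = 0.114; adjusted p = 0.398 with an estimated correlation).

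The count of 148 changed with the arrays used, and how far depended on which were left out. It was 143 without EpiSC5, 85 without EpiSC1, 91 without EpiSC2, 77 without aCF1, 73 without aCF2, 90 without aCF3, 91 without aCF4, 87 without aCF5, and 50 without both aCF4 and aCF5, a set chosen after seeing the data. In a fit of all 3 groups it was 369, 178 higher and 191 lower in EpiSC, so the majority of higher probe sets does not hold there. Of 39 calls of named genes, leaving out both these arrays ended 26, quantile normalization 12 and a trended and robust fit 11. Besides those given above, quantile normalization ended, among others, the calls of Dmkn (0.895), Vegfd (0.0956), Des (0.0906), Tpi1 (0.0758) and Slc16a3 (0.0532). The trended and robust fit ended, among others, those of Heyl, Col15a1 and Tpi1 (adjusted p = 1 for each), Vegfd (0.342) and Gins2 (0.165). Its trend followed centred means and not expression levels, so these losses cannot tell a weak call from an unsuitable trend.

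**Figure D3:**
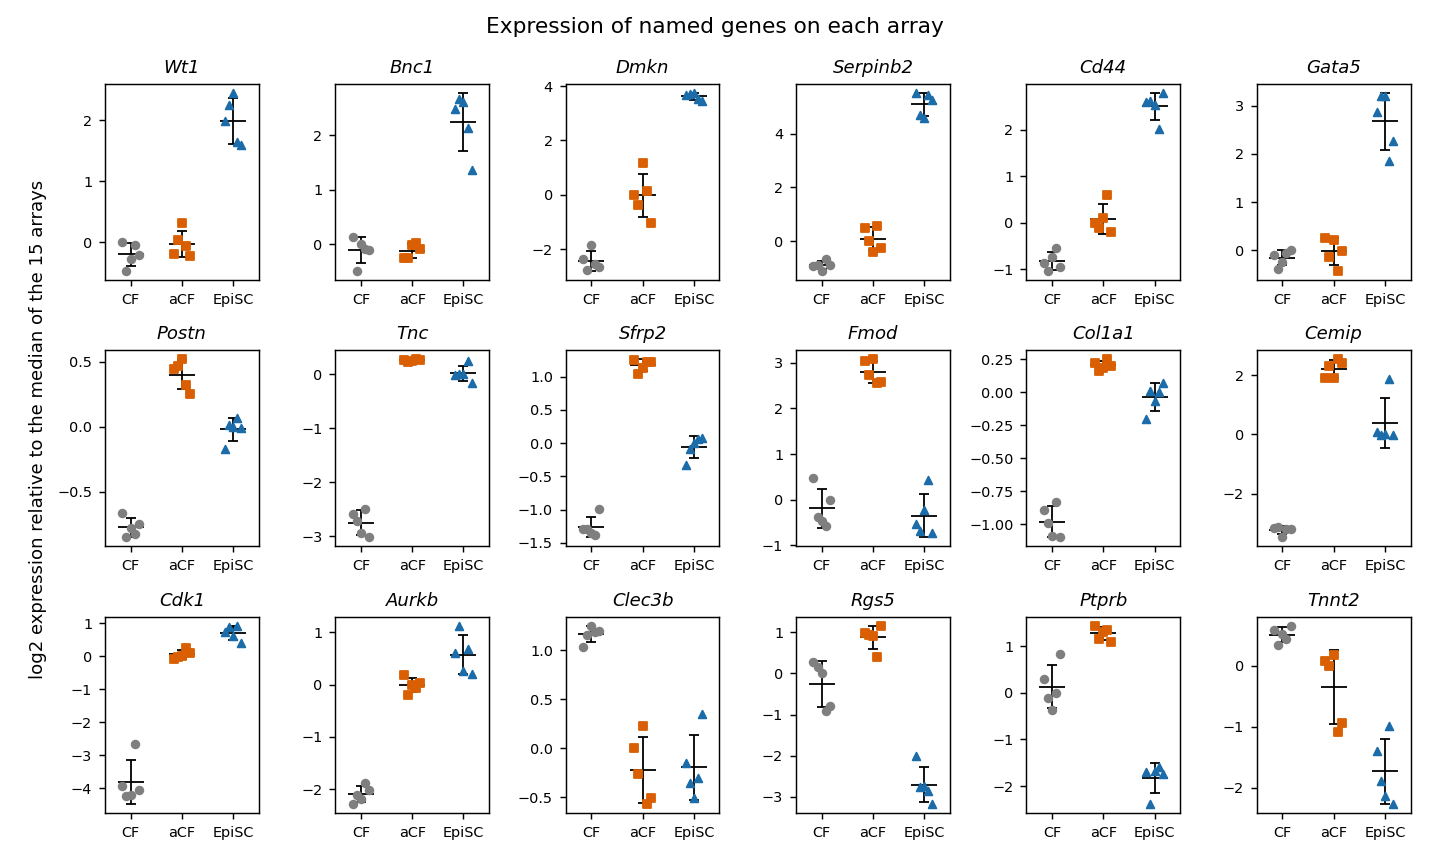
Expression of 18 genes on each array, as log2 relative to the median of the 15 arrays (vertical axes), for the 3 groups (horizontal axes). Points are arrays, and the bar and whiskers give the mean and SD of 5 arrays. All 5 EpiSC arrays lie above all aCF and CF arrays for Wt1, Bnc1, Dmkn, Serpinb2, Cd44 and Gata5.

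The comparison of aCF with CF asks how ventricular fibroblasts of infarcted hearts differ from those of unstressed hearts. No sham-operated group is named, so any effect of the procedure cannot be told apart from infarction. Genes of matrix production and of fibroblast activation were among those that rose. Cemip, which depolymerizes hyaluronan, rose by 5.44 ± 0.13 (SE, n = 5 arrays per group), Tnc, the matricellular tenascin C, by 3.00 ± 0.10, Col1a1 by 1.18 ± 0.06 and Postn by 1.17 ± 0.07. The mitotic kinase Cdk1 rose by 3.87 ± 0.27. Of 31 cell cycle genes 18 rose, and the list passed camera (adjusted p = 0.0523 with an estimated correlation). Of 14 markers of resting fibroblasts 6 fell, and that list passed camera too (adjusted p = 0.0919 with an estimated correlation). Among them was the atypical chemokine receptor Ackr3, which fell by 1.44 ± 0.10 on the log2 scale. In limma's moderated test 340 probe sets passed, 269 higher and 71 lower in aCF, of which 303 carried a name. Of 36 gene lists 16 passed camera, 11 shifted upward and 5 downward, 1 passed with an estimated correlation, and fry called 24. In 17.2% of the paired rows the groups did not overlap, against 0.794% by chance.

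The largest increases were those of Cemip (adjusted p = 1.72e-08), the P-cadherin gene Cdh3 (4.62 ± 0.12, adjusted p = 3.69e-08) and Ddah1, which degrades inhibitors of nitric oxide synthase (4.33 ± 0.13, adjusted p = 1.13e-07). They were followed by the kinesin Kif26b (4.00 ± 0.18, adjusted p = 1.01e-05) and Cdk1 (adjusted p = 0.000636). Wfdc18 (3.77 ± 0.22, adjusted p = 0.000122), the spindle protein Fam83d (3.66 ± 0.25, adjusted p = 0.000535) and Ecrg4 (3.49 ± 0.22, adjusted p = 0.000243) completed the 8 largest. The largest decreases were those of the carboxylesterase Ces1d (-2.50 ± 0.21, adjusted p = 0.00507), the organic anion transporter Slco2b1 (-2.50 ± 0.15, adjusted p = 0.000154) and the enkephalin precursor Penk (-2.27 ± 0.18, adjusted p = 0.00239). Icosl (-2.21 ± 0.16, adjusted p = 0.00105), Prex2 (-2.0 ± 0.15, adjusted p = 0.00115), Il6ra (-1.99 ± 0.16, adjusted p = 0.00338) and Olfml2a (-1.92 ± 0.17, adjusted p = 0.0067) also fell. The neurotrophin receptor Ntrk3 (-2.07 ± 0.19, adjusted p = 0.0106) lost its call without CF2, CF3, CF4, CF5, aCF2 or aCF4 (up to 0.0738). For each gene named as past the threshold in this comparison, all 5 aCF arrays lay on the same side of all 5 CF arrays. For the largest differences this was a condition of being named.

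Of 16 activated fibroblast and myofibroblast markers 13 rose and 0 fell, and 14 rose and 0 fell adjusted over the list alone (median 1.49, camera adjusted p = 1.87e-17). This list also passed with an estimated correlation (adjusted p = 0.00474). Besides Ddah1, the 4 members with the smallest P were Tnc (adjusted p = 2.96e-07), Sfrp2 (2.44 ± 0.08, adjusted p = 3.86e-07) and Postn (adjusted p = 9.41e-05). Of 17 fibrillar and fibril-associated collagens 7 rose and 0 fell, and 8 rose and 1 fell adjusted over the list alone (median 0.19, camera adjusted p = 3.76e-05; adjusted p = 0.122 with an estimated correlation). Col1a2 rose by 1.27 ± 0.06 (adjusted p = 7.46e-06), Col5a2 by 1.48 ± 0.08 (adjusted p = 2.87e-05), Col1a1 (adjusted p = 5.7e-05) by the amount above and Col11a1 by 2.54 ± 0.16 (adjusted p = 0.000222). Of 17 collagen processing genes 4 rose and 1 fell, and 10 rose and 1 fell adjusted over the list alone (median 0.33, camera adjusted p = 3.16e-05; adjusted p = 0.122 with an estimated correlation). The prolyl hydroxylase subunit P4ha3 rose by 3.41 ± 0.14 (adjusted p = 4.44e-06) and the collagen chaperone Serpinh1 by 0.79 ± 0.06 (adjusted p = 0.00151).

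Of 31 cell cycle genes 18 rose and 0 fell, and 29 rose and 0 fell adjusted over the list alone (median 1.47, camera adjusted p = 7.4e-29; adjusted p = 0.0523 with an estimated correlation). The mitotic kinase Aurkb rose by 2.09 ± 0.09 (adjusted p = 6.14e-06), the mitotic kinesin Kif23 by 2.81 ± 0.14 (adjusted p = 3.24e-05), cyclin A2 (Ccna2) by 1.92 ± 0.11 (adjusted p = 8.74e-05) and thymidylate synthase (Tyms) by 1.24 ± 0.08 (adjusted p = 0.000345). Growth factors were shifted upward, with 7 of 24 risen and 0 fallen, and 11 risen and 1 fallen adjusted over the list alone (median 0.37, camera adjusted p = 6.63e-05; adjusted p = 0.122 with an estimated correlation). Mdk rose by 1.26 ± 0.07 (adjusted p = 6.74e-05), Ptn by 2.05 ± 0.16 (adjusted p = 0.00201), Nrg1 by 2.48 ± 0.20 (adjusted p = 0.00258) and Pdgfc by 2.42 ± 0.19 (adjusted p = 0.00259).

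Of 14 markers of resting cardiac fibroblasts 6 fell and 0 rose, and 9 fell and 0 rose adjusted over the list alone (median -0.63, camera adjusted p = 4e-09; adjusted p = 0.0919 with an estimated correlation). Beside Ackr3 (adjusted p = 0.000507), Clec3b, which encodes tetranectin, fell by 1.38 ± 0.14 (adjusted p = 0.0323), a call that held only without aCF3 (up to 0.194 otherwise). Immediate-early and dissociation-associated genes were lower in aCF, with 2 of 20 fallen and 0 risen, and 10 fallen and 1 risen adjusted over the list alone (median -0.56, camera adjusted p = 0.000161; adjusted p = 0.148 with an estimated correlation). Ppp1r15a, a stress-response phosphatase subunit, fell by 0.89 ± 0.07 (adjusted p = 0.00326). Epicardial markers did not shift as a list by camera (1 of 17 risen, 0 fallen, with 3 risen and 1 fallen adjusted over the list alone, median 0.12, camera adjusted p = 0.108). By fry they moved upward on balance (fry adjusted p = 0.000686). The list passed camera without aCF5 (adjusted p = 0.0308) and without aCF4 and aCF5 together (adjusted p = 0.0101), with a range of 0.0101 to 0.213 over the settings. Its risen member was Cdh3. Wt1 (0.17 ± 0.12), Tbx18 (0.22 ± 0.14) and Tcf21 (-0.38 ± 0.09) did not pass (adjusted p = 1 for each).

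Markers of other cell types moved with the same comparison. Of 19 macrophage and monocyte markers 1 rose, the protease Ctss (1.00 ± 0.08, adjusted p = 0.00213), and 5 rose adjusted over the list alone (median 0.29, camera adjusted p = 0.000342; adjusted p = 0.133 with an estimated correlation). Of 14 pericyte and smooth muscle markers 2 rose and 7 rose adjusted over the list alone (median 0.66, camera adjusted p = 0.00177; adjusted p = 0.294 with an estimated correlation), including Tagln (2.36 ± 0.14, adjusted p = 0.000111), which myofibroblasts also express. In the endothelial list 0 of 17 markers passed over all genes in limma, where 2 lay higher and 8 lower at an unadjusted p under 0.05. Of the endothelial markers 1 rose and 3 fell adjusted over the list alone (median -0.26, camera adjusted p = 0.0428, fry adjusted p = 0.0608; adjusted p = 0.463 with an estimated correlation). The camera call of that list was lost without CF1 (adjusted p = 0.059), CF4 (0.0754), CF5 (0.0958), aCF3 (0.0516), aCF4 (0.0642) or aCF5 (0.0825), without aCF4 and aCF5 together (0.189), and in a fit of all 3 groups (0.0962), with a range of 0.012 to 0.189 over the settings. Of 22 heart muscle markers 0 passed in limma over all genes and 0 adjusted over the list alone, whereas 0 lay higher and 10 lower at an unadjusted p under 0.05. That list passed camera (median -0.31, camera adjusted p = 0.00186, fry adjusted p = 0.0608; adjusted p = 0.434 with an estimated correlation). This call was lost without aCF4 and aCF5 (adjusted p = 0.137, with a range of 0.000138 to 0.137 over the settings). The median of the heart muscle list was -0.44 in aCF4 and -0.26 in aCF5, against 0.01 in aCF1, 0.08 in aCF2 and 0.19 in aCF3.

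The count of 340 was 203 without CF2, 197 without CF3, 220 without CF5, 213 without aCF2, 215 without aCF5, and 144 without both aCF4 and aCF5. Of 47 calls of named genes, leaving out both these arrays ended 10, a fit of all 3 groups 8, a trended and robust fit 8 and quantile normalization 6. The 3-group fit ended, among others, the calls of Ppp1r15a (0.397), Ces1d (0.347), Penk (0.176) and Slco2b1 (0.0598). The trended and robust fit ended, among others, those of Clec3b (0.245), Ctss (0.126), Ppp1r15a (0.0792) and Ntrk3 (0.0521), and quantile normalization ended that of Clec3b (0.21). Quantile normalization also reduced Cdh3 to 3.70, Cdk1 to 3.20 and Fam83d to 3.01.

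**Figure D4:**
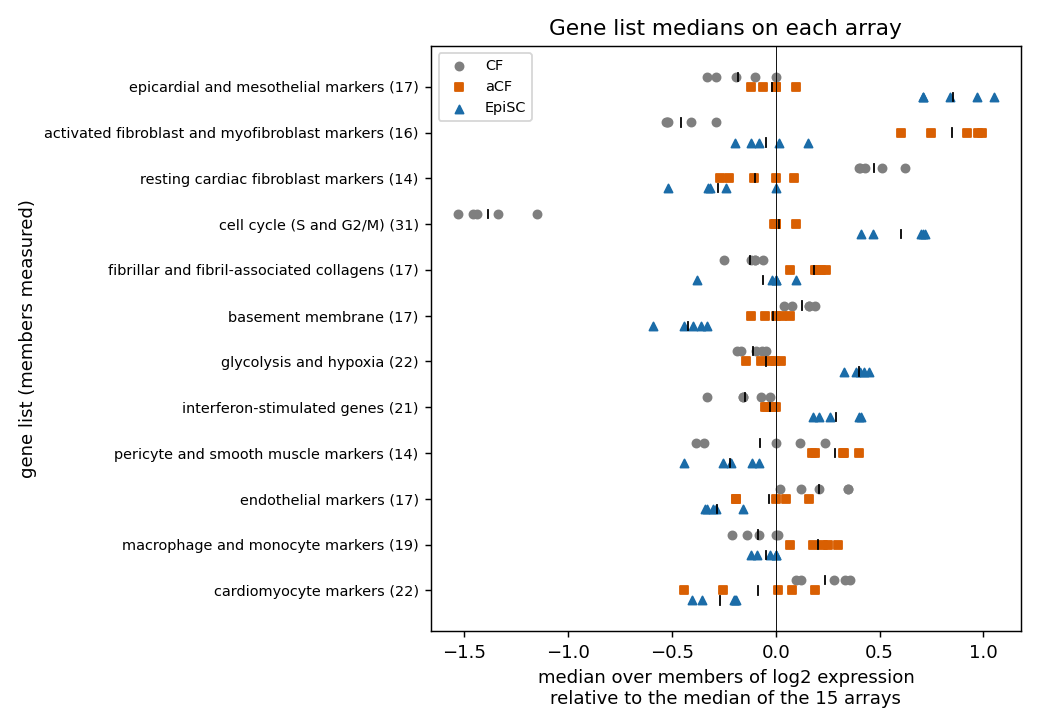
Median over the measured members of 12 gene lists on each array, as log2 relative to the median of the 15 arrays (horizontal axis), with 1 point per array and a bar at the mean of each group. The cell cycle list lies between -1.53 and -1.15 in CF and between 0.41 and 0.72 in EpiSC, and the activated fibroblast list between 0.61 and 1.00 in aCF.

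EpiSC were also set against CF, a secondary comparison that the design text does not name. In it tissue origin, isolation and infarction differ together. EpiSC expressed more Dmkn (6.05 ± 0.16, SE, n = 5 arrays per group, adjusted p = 4.58e-08) and Cdh3 (4.73 ± 0.14, adjusted p = 1.37e-07). Of 17 epicardial markers 8 had risen and 0 fallen, and 10 risen and 1 fallen adjusted over the list alone (median 1.36, camera adjusted p = 4.36e-05; adjusted p = 0.0796 with an estimated correlation). Of 31 cell cycle genes 25 rose and 0 fell, and 30 rose adjusted over the list alone (median 2.29, camera adjusted p = 5.47e-24; adjusted p = 0.0796 with an estimated correlation). Ccna2 was higher by 2.34 ± 0.12 (adjusted p = 4.18e-05) and Gins2 by 2.19 ± 0.11 (adjusted p = 4.84e-05). Basement membrane genes were lower, with 9 of 17 fallen and 0 risen, and 10 fallen and 1 risen adjusted over the list alone (median -0.73, camera adjusted p = 6.09e-05; adjusted p = 0.0517 with an estimated correlation). Col4a3 was among them (-2.49 ± 0.17, adjusted p = 0.000779). In limma 647 probe sets passed, 438 higher and 209 lower in EpiSC, and in 25.1% of the paired rows the groups did not overlap, against 0.794% by chance. Of 36 gene lists 15 passed camera, 11 shifted upward and 4 downward, 0 passed with an estimated correlation (9 at an unadjusted p under 0.05), and fry called 27. For each gene named as past the threshold here, all 5 EpiSC arrays lay on the same side of all 5 CF arrays.

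Activated fibroblast markers were higher in EpiSC than in CF, with 7 of 16 risen and 0 fallen, and 8 risen and 2 fallen adjusted over the list alone (median 0.45, camera adjusted p = 0.00796; adjusted p = 0.492 with an estimated correlation). Tnc rose by 2.76 ± 0.11 (adjusted p = 4.5e-06) and the tropomyosin Tpm2 by 2.02 ± 0.10 (adjusted p = 2.15e-05). Resting fibroblast markers were lower, with 2 of 14 fallen and 12 fallen adjusted over the list alone (median -0.87, camera adjusted p = 1.41e-07; adjusted p = 0.145 with an estimated correlation). The fallen members were Clec3b (-1.36 ± 0.14, adjusted p = 0.0408), whose call held only without EpiSC5 (up to 0.248 otherwise), and the lipoprotein lipase Lpl (-0.78 ± 0.08, adjusted p = 0.0475), whose call held only without CF5 (up to 0.278 otherwise). Of 21 interferon-stimulated genes 5 rose and 0 fell, and 12 rose and 1 fell adjusted over the list alone (median 0.57, camera adjusted p = 6.09e-05; adjusted p = 0.198 with an estimated correlation), with Irf7 higher by 2.29 ± 0.15 (adjusted p = 0.000483). Glycolysis genes were higher, with 6 of 22 risen and 0 fallen, and 10 risen and 2 fallen adjusted over the list alone (median 0.41, camera adjusted p = 0.000417; adjusted p = 0.135 with an estimated correlation). Heart muscle markers were lower, with 3 of 22 fallen and 0 risen, and 12 fallen and 1 risen adjusted over the list alone (median -0.62, camera adjusted p = 5.72e-06; adjusted p = 0.0796 with an estimated correlation). The ventricular light chain Myl2 was among them (-2.76 ± 0.23, adjusted p = 0.00462). The count of 647 was 381 without CF1, 389 without CF2, 369 without CF3, 421 without CF4 and 405 without CF5. A fit of all 3 groups ended the calls of Myl2 (0.305) and Myl3 (0.116). Quantile normalization ended those of Clec3b (0.0788) and Lpl (0.132), as did a trended and robust fit (0.226 and 0.0742), and array weights ended that of Lpl (0.102). Quantile normalization reduced Dmkn to 4.84 and Cdh3 to 3.78.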

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

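The tests weighed here were all chosen after the results they bear on had been seen, the other splits of the arrays included. Of 100 splits of the 10 arrays in each comparison, 1 gave as many probe sets past the threshold, the real split itself. The highest other split gave 1 against the real 148 for EpiSC against aCF, 2 against 340 for aCF against CF, and 1 against 647 for EpiSC against CF. Chance assignment of the arrays is excluded as the source of these counts. For a lower share of fibroblasts, weighed last, the bound was replaced after its values were seen, and the earlier one, which asked that 2 lists each separate all arrays in opposite directions, was not met.

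Genes known to work together did not vary together under the identifiers as deposited. Noise in the arrays is argued against, since the cell cycle genes reached a correlation within groups of 0.283 at a row offset of 6900. Names attached to the wrong identifiers are argued against too, since only 2 of 19508 annotated identifiers name another chromosome than that of their gene. Values displaced against the identifiers may account for it: with the rows paired at that offset, and 3 rows more from chromosome 10 on, 19 of the 35 other lists exceeded the 95th percentile of random lists, against 0 as deposited. How the displacement arose was not tested, and no biological explanation was tested.

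Heart muscle markers as a list passed camera downward from CF to EpiSC (adjusted p = 0.0796 with an estimated correlation) and from CF to aCF, where 0 of 22 passed singly and the call was lost with an estimated correlation (0.434) and without aCF4 and aCF5 (0.137). Carried-over heart muscle RNA may contribute, since the markers varied together within groups, taken over all 3 groups (mean correlation 0.321, above the 95th percentile of random lists, 0.0522). The correlation estimated by camera was 0.424 for aCF against CF but only 0.076 for EpiSC against CF. This ground for carry-over therefore bears on the aCF arrays and hardly on the difference from CF to EpiSC. From CF to EpiSC, Myl2 differed by -2.76, Myl3 by -2.19 and Tnnt2 by -2.24, but Actc1 by only -0.29 and Ckm by -0.14; from CF to aCF these 5 differed by -1.23, -0.89, -0.86, -0.076 and -0.13. Because levels are lost, saturation of the last pair could not be examined, and carry-over and a biological difference cannot be told apart. Infarction and the different release of EpiSC from the heart stay open as untested causes.

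Markers of other cell types differed between aCF and CF. A lower share of fibroblasts among the aCF, made up by all 4 other cell types alike, would raise all 4 lists tested. The heart muscle median differed by -0.32 (exact permutation p = 0.0317, Benjamini-Hochberg adjusted p = 0.0423) and the endothelial one by -0.24 (exact p = 0.0476, adjusted 0.0476). The macrophage median differed by 0.29 (exact p = 0.00794, adjusted 0.0317) and the mural one by 0.36 (exact p = 0.0238, adjusted 0.0423). Within arrays, the macrophage median minus the endothelial one was higher in aCF than in CF by 0.53. The mural minus the endothelial one was higher by 0.60, with an SD of 0.39 in CF. In each case all aCF arrays lay above any CF array (exact permutation p = 0.00794, the smallest possible, adjusted 0.0238 over 6 pairs of lists). For the mural list this separation was narrow, since aCF2 (mural 0.19, endothelial 0.16) lay close to CF1 (0.235 and 0.21). The CF arrays were also split, with mural medians of -0.385 in CF4 and -0.345 in CF5 against 0.235, 0.115 and 0 in CF1, CF2 and CF3. The macrophage and endothelial medians, which moved apart, argue against a share lost alike to all 4 cell types as the whole cause. The mural list holds Tagln, which myofibroblasts also express, so its rise need not reflect a share of cells. A lower share of fibroblasts taken up by only some cell types could not be examined this way and stays open. More macrophages after infarction stay open as an untested biological explanation.

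An array far from the other 4 of its group was seen in 33 of 474 groups of values tested (6.96%), where chance gives about 1 in 20. In EpiSC4, Cemip was 1.87 (others -0.03 to 0.08), Tagln 0.72 (-0.04 to 0.05), Cnn1 1.85 (0 to 0.53), Tpm2 0.86 (0.42 to 0.51) and Aqp1 1.77 (2.28 to 2.39), and the endothelial median was -0.16 (-0.34 to -0.29). In EpiSC1, Tpi1 was 0.68, C1qc 0.22, the cardiac transcription factor median -0.155 and the fibrillar collagen median -0.38. Ptprb was -2.38 in EpiSC2 and Cxcl13 was 5.26 in EpiSC3. In aCF2, Mcm5 was -0.39 and Olfr558 1.95. In aCF3, Ddah1 was 1.52 and Tbx18 -0.46. In aCF4, Heyl was -0.11 and Mdk 0.54. In aCF5, Birc5 was 0.27 and the cell cycle median 0.10. In CF1, Des was -1.27, Ntrk3 1.41, Ptn 0 and Sfrp1 -0.25. Lcn2 was -2.09 in CF2. In CF3, Cemip was -3.47 and the hyaluronan and proteoglycan median -0.05. In CF4, Cdk1 was -2.65 and Cxcl13 -0.43. In CF5, Fam83d was -2.61, P4ha3 -2.54, Sfrp2 -0.99 and Vegfd -0.90.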

How the results depend on the processing

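Settings are ordered as EpiSC against aCF, aCF against CF and EpiSC against CF. The identifiers as deposited and the fit without aCF4 and aCF5 were chosen after seeing the data. Against 148, 340 and 647 probe sets, Benjamini-Hochberg adjustment gave 2135, 4023 and 7157, with 47.9%, 48.2% and 45.05% higher against 60.1%, 79.1% and 67.7%. A less strict adjustment must give more. In the paired rows 879 of 1823, 1674 of 3038 and 2700 of 4995 were higher, and in the leading unnamed rows 144 of 312, 266 of 985 and 524 of 2162, so for the comparisons with CF the unnamed rows turn the majority. A shared fit of the 3 groups gave 369 (178 higher and 191 lower) and 1060 (669 and 391) for the comparisons with EpiSC, a trended and robust fit 97 (65 and 32) and 212 (196 and 16) for the comparisons with aCF, and the fit without aCF4 and aCF5 50 and 144; the cause was not tested beyond the fewer arrays of the last. Leaving out each array gave 73 to 143, 197 to 272 and 369 to 557. With the replicate number as a block the counts were 41 (34 higher and 7 lower), 94 (79 and 15) and 166 (129 and 37). The labels do not say that same-numbered aCF and EpiSC share a heart. After group means were removed, same-numbered arrays of these 2 groups correlated by 0.034, 0.027, 0.053, 0.172 and -0.003. Of the EpiSC arrays 2 of 5 correlated best with their own number, so the numbers were not taken as pairs. The block also ended the list calls of BMP and TGF-beta components (EpiSC against aCF, 0.0531) and endothelial markers (aCF against CF, 0.0508). A 2-fold minimum, quantile normalization, array weights, averaged probe sets, paired rows alone and their medians subtracted left each count within 1.5 times.

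Of 36 lists 18, 16 and 15 passed camera. With an estimated correlation 0, 1 and 0 passed (12, 11 and 9 at an unadjusted p under 0.05), while fry called 24, 24 and 27. With the identifiers as deposited camera called 0, 0 and 0 (0, 0 and 0 unadjusted) and fry 3, 4 and 17. Leaving out each array gave 17 to 20, 14 to 18 and 15 to 16 lists.

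Of 39, 47 and 16 named genes past the threshold, 4, 26 and 8 stayed past it in every setting, and the block ended 28, 18 and 8 calls. Of 1422, 1224 and 272 values for named genes, 1155, 1101 and 235 kept direction and side, 228, 115 and 37 were no longer past, 38, 8 and 0 newly past, and 1 reversed: Tbx18, EpiSC against aCF, -0.0105 without aCF3, with other omissions up to 0.1945 (without EpiSC1), and the cause was not tested. Subtracting array medians moved nothing, as they were 0. The percentile filters, 20th and 40th, were not run because levels are lost, which also hides signal over background.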

Other observations

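The tests of an atrial source of Myl7, and the choice of lists described, were made after the results had been seen. Cholesterol synthesis genes lay higher in EpiSC than in aCF. Of 13 measured, 0 passed over all genes in limma, where 10 lay higher and 0 lower at an unadjusted p under 0.05. Adjusted over the list alone, 4 rose and 0 fell (median log2 difference 0.56, camera adjusted p = 8.52e-06, fry adjusted p = 0.0039; adjusted p = 0.191 with an estimated correlation). The 4 with the smallest P were Pmvk (0.93 ± 0.11, SE, n = 5 arrays per group), Fdps (1.01 ± 0.14), Nsdhl (0.64 ± 0.11) and Cyp51 (0.95 ± 0.16), enzymes of the mevalonate and sterol pathway that did not pass over all genes. Each was higher in all 5 EpiSC arrays than in any aCF array. Complement genes lay lower in EpiSC, with 0 of 13 past the threshold over all genes in limma, where 0 lay higher and 7 lower at an unadjusted p under 0.05. Adjusted over the list alone, 5 fell and 0 rose (median -0.24, camera adjusted p = 0.0128, fry adjusted p = 0.00371; adjusted p = 0.148 with an estimated correlation). The macrophage-derived C1qa (-1.11 ± 0.27) and C1qb (-0.26 ± 0.064) were among the members named, and neither passed over all genes (adjusted p = 1 for each). Fibrillar collagens as a list lay lower in EpiSC than in aCF (median -0.39, camera adjusted p = 0.000633; adjusted p = 0.148 with an estimated correlation). In that list 0 of 17 were past the threshold in limma over all genes, where 3 lay higher and 11 lower at an unadjusted p under 0.05, and 2 risen and 6 fallen adjusted over the list alone. Oxidative phosphorylation genes lay slightly higher (median 0.14, camera adjusted p = 0.00438; adjusted p = 0.191 with an estimated correlation). Here 0 of 28 were past the threshold in limma, where 14 lay higher and 1 lower at an unadjusted p under 0.05, and 1 risen and 1 fallen adjusted over the list alone. BMP and TGF-beta components lay lower (median -0.074, camera adjusted p = 0.0399; adjusted p = 0.108 with an estimated correlation). Among them 0 of 27 were past the threshold in limma, where 4 lay higher and 8 lower at an unadjusted p under 0.05, and 1 risen and 5 fallen adjusted over the list alone. This call was lost without EpiSC4 (adjusted p = 0.0555) or aCF2 (adjusted p = 0.0703) and in a fit of all 3 groups (adjusted p = 0.0535), with a range of 0.0234 to 0.0703 over the settings.

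Regulators and markers of mesenchymal transition were higher in aCF than in CF, with 3 of 10 risen and 0 fallen, and 5 risen and 1 fallen adjusted over the list alone (median 0.38, camera adjusted p = 0.000161; adjusted p = 0.122 with an estimated correlation). Fibronectin (Fn1) rose by 1.29 ± 0.06 (limma, adjusted p = 6.97e-06) and the mesenchymal cadherin Cdh11 by 1.34 ± 0.08 (adjusted p = 0.000174). The transcription factor Prrx2 rose by 1.06 ± 0.11 (adjusted p = 0.0283), a call that held only without CF4 or aCF3 (up to 0.155 otherwise). Ribosomal protein genes were slightly higher in aCF as a list, with 0 of 18 past the threshold in limma, where 11 lay higher and 0 lower at an unadjusted p under 0.05. Adjusted over the list alone, 4 rose (median 0.14, camera adjusted p = 0.000164, fry adjusted p = 0.000134; adjusted p = 0.299 with an estimated correlation). Basement membrane genes lay lower in aCF than in CF (median -0.23, 0 of 17 risen and 1 fallen, 2 and 6 adjusted over the list alone, camera adjusted p = 0.00863; adjusted p = 0.371 with an estimated correlation). Matrix proteases and inhibitors lay higher (median 0.17, 3 of 21 risen and 0 fallen, 8 and 1 adjusted over the list alone, camera adjusted p = 0.0393; adjusted p = 0.148 with an estimated correlation). The call was lost without aCF1 (adjusted p = 0.0566, with a range of 0.0232 to 0.0566 over the settings). Oxidative phosphorylation genes lay higher (median 0.093, 0 of 28 past the threshold in limma, where 10 lay higher and 1 lower at an unadjusted p under 0.05, and 3 risen adjusted over the list alone, camera adjusted p = 0.0344; adjusted p = 0.401 with an estimated correlation). That call was lost without CF1 (0.0542), CF2 (0.0644), aCF1 (0.0603) or aCF3 (0.0558), with a range of 0.0126 to 0.0644 over the settings.

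Between EpiSC and CF 7 further lists passed camera. Endothelial genes were lower (median -0.66, 1 of 17 risen and 2 fallen, 2 and 8 adjusted over the list alone, camera adjusted p = 0.000108; adjusted p = 0.135 with an estimated correlation). Cholesterol synthesis (median 0.71, 3 of 13 risen, 9 adjusted over the list alone, camera adjusted p = 0.000255; adjusted p = 0.399 with an estimated correlation) and ribosomal protein genes (median 0.20, 1 of 18 risen, 9 adjusted over the list alone, camera adjusted p = 0.000412; adjusted p = 0.387 with an estimated correlation) were higher. Mesenchymal transition regulators were higher too (median 0.52, 3 of 10 risen, 6 and 1 fallen adjusted over the list alone, camera adjusted p = 0.00796; adjusted p = 0.135 with an estimated correlation). Oxidative phosphorylation genes were higher (median 0.18, camera adjusted p = 0.000573; adjusted p = 0.387 with an estimated correlation), with 0 of 28 past the threshold in limma, 19 higher and 1 lower at an unadjusted p under 0.05, and 10 risen and 1 fallen adjusted over the list alone. Collagen processing genes (median 0.44, 4 of 17 risen, 9 risen and 3 fallen adjusted over the list alone, camera adjusted p = 0.0189; adjusted p = 0.544 with an estimated correlation) lost their call without EpiSC5 (adjusted p = 0.0705, range 0.00787 to 0.0705). Chemokines (median 0.15, 3 of 27 risen, 6 adjusted over the list alone, camera adjusted p = 0.0238; adjusted p = 0.182 with an estimated correlation) lost theirs without EpiSC4 (adjusted p = 0.0524, range 0.00718 to 0.0524).

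A hypothesis of atrial muscle RNA in the EpiSC was tested after Myl7, the atrial light chain, had been seen to differ by 2.38 ± 0.28 between EpiSC and aCF without passing the threshold (adjusted p = 0.13). Per the protocols the atria were removed for CF and aCF only, so atrial RNA could have entered the EpiSC. Among other atrial genes Nppa differed by -0.76 ± 0.45, Sln by 0.038 ± 0.084, Myl4 by 0.056 ± 0.090 and Bmp10 by -0.014 ± 0.063, with a median of 0.012. Atrial muscle would bring its other transcripts too, and their median lay below the difference of Myl7 by more than their SD of 0.40 and the SE of Myl7 together. These genes thus did not rise with Myl7. The test cannot decide on atrial RNA as the source, because levels are lost and the response of these probe sets to carried-over RNA is unknown. From CF to EpiSC, Actc1 (-0.29) and Ckm (-0.14) likewise hardly differed where Myl2 differed by -2.76. The list was also written after the values of Myl7 and Nppa had been seen. The bound was replaced after the values were seen too, and the earlier one, a median at or below 0, was not met. What raised Myl7 was not tested further.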
